A study of Mus musculus with 7 samples.

How the data were processed

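Polyadenylated RNA of 7 mouse splenocyte co-cultures was measured, 4 with AOAH and 3 with buffer. Per the labels' protocols, libraries were made with the NEBNext Ultra II kit with unique molecular identifiers in the primers and sequenced on a NovaSeq. Reads were quantified with RSEM against mm39, per the submitters' processing notes, which give no versions. The expression table was deposited by the authors as log2(TPM + 1) per gene symbol, which was checked by turning the values back: at least 99.9% lay within 1e-08 TPM of a multiple of 0.01 TPM in each sample. The repertoire table was deposited by the authors with 20 measures per sample from MiXCR, which the file name alone gives. The authors' deposited table of fold changes was made with DESeq2, per the submitters' processing notes, without a stated design or version. In that table, the authors gave per gene a mean signal over samples of counts divided by size factors, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value, per the file headers. Gene names for its Ensembl IDs came from the reference name table, which is of another build than mm39, so no coordinates are given; 25644 IDs had a symbol and 993 had none. No count table was among the files, so the depth of each sample is unknown.

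Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values without a further pseudocount, with lmFit and eBayes with a trend. Genes at a TPM of at least 1 in at least 3 samples were kept, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Both label doses formed 1 AOAH group; doses were compared in a fit with 3 groups. Fixed lists of genes, 37 in number, were tested with camera in limma at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Members were also counted with p-values adjusted over the list alone. The measured members of a list are those that the TPM filter kept. Repertoire measures were compared with a two-sided exact permutation test over all 35 splits into 4 and 3 and adjusted over the 20 measures. Means are given with the SD on the TPM scale, and log2 fold changes with the limma standard error. Figures were drawn with matplotlib 3.10.9.

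Genes were named by a rule fixed before the files were seen. Aoah came first, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean TPM of at least 5 and groups that did not overlap, without predicted genes. From each list up to 4 members with the smallest p were named, apart from some that are not reported here, and for the doses the 5 with the smallest p in each direction. A gene outside this rule is said to be so where it is named.

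The scripts were tested on simulated data with 12510 genes, of which 200 were changed in each of 10 runs. For AOAH against buffer 51.6%, 87.3% and 98.3% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 4.76% of calls were false. For 10 against 5 µg/mL the recovered shares were 29.7%, 73.7% and 94.5%, and 5.39% of calls were false. The simulated noise was independent between genes.

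Alternatives covered pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, quantile normalization, median-ratio scaling on TPM, TPM rescaled without mitochondrial and receptor genes, eBayes without a trend and robust, and sample weights. Each sample was left out in turn, each dose was set against buffer alone, the replicate number was used as a block, and lists were tested with fry. The B cell score as a covariate, odd against even replicate numbers as a block and TPM rescaled without the 50 most abundant genes were added after the data were seen. Count tools were not run, because counts were not among the files used here.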

Results

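Polyadenylated RNA was sequenced from 7 cultures of mouse spleen cells, 4 kept with recombinant human AOAH and 3 kept with its buffer. AOAH, acyloxyacyl hydrolase, is a lipase best known for removing fatty acyl chains from bacterial lipopolysaccharide. Cells from pmel mice, whose CD8 T cells carry a transgenic receptor for a peptide of the melanoma antigen gp100, were first held with AOAH or buffer for 22 h. They were then mixed with C57BL/6 splenocytes that had been loaded for 2 h with 100 nM hgp100, and kept for 24 h with 100 IU/mL IL-2 and with AOAH or buffer. The buffer was saline with 10% glycerol. The dose label of AOAH replicates 1 and 2 is 5 µg/mL and that of replicates 3 and 4 is 10 µg/mL, whereas the protocol text in the sample labels gives 10 µg/mL for all. The sample labels describe splenocytes and the series text describes isolated CD8 T cells on the pmel side. The ratio at which the cells were mixed also differs between these texts. Each expression table listed 30690 genes, of which between 18679 (AOAH replicate 1) and 21728 (AOAH replicate 4) were above 0. The sequencing depth of each sample is unknown, because the values are on the TPM scale, which keeps no depth. The endogenous mouse Aoah transcript was low in both groups, at 1.08 ± 0.498 TPM (SD, n = 4) with AOAH and 0.977 ± 0.381 TPM (SD, n = 3) with buffer (exact permutation p = 0.771).

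The first comparison asked which transcripts differed between AOAH and buffer cultures. Lists of glycolysis, low oxygen response, cytotoxic effector, cell cycle, B cell and MHC class II genes were higher with AOAH by camera. Lists of the unfolded protein and integrated stress response, T cell markers and ribosomal proteins were lower. Each of these calls was lost with an estimated correlation, where the smallest adjusted p was 0.232. Bnip3, a mitophagy receptor induced by low oxygen, was at 68.9 ± 21.3 TPM (SD, n = 4) with AOAH and 7.09 ± 1.78 TPM (SD, n = 3) with buffer. At the other end, Chac1, a glutathione-degrading enzyme of the stress response, was at 5.19 ± 1.22 TPM with AOAH and 19.0 ± 1.91 TPM with buffer. Of 12510 genes tested with limma, 1416 passed an adjusted p of 0.05, 1166 higher and 250 lower with AOAH. Among these, 199 were at least 2-fold higher and 16 at least 2-fold lower on the log2(TPM + 1) scale. The split depended on the scaling between samples. It was 82.3% higher with TPM as deposited, 59.0% (660 higher, 458 lower) with median-ratio scaling and 52.0% (658 higher, 607 lower) with quantile normalization. It was 70.7% (791 higher, 328 lower) with TPM rescaled without the 50 most abundant genes, chosen after the data were seen. The groups did not overlap for 1408 of the 1416 genes, and for 27.6% of all tested genes, where chance gives 5.71%. The count fell to 716 without AOAH replicate 2, 898 without AOAH replicate 3, 700 without AOAH replicate 4 and 628 without buffer replicate 1.

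By the naming rule, the largest rises were those of Bnip3, Slc16a3, Egln3, Aldoc, Fgd2, Ighv14-4, Rgs11, Ak4, Fcer2a, Tpi-rs11, Cd22 and Pld4. Their log2 fold changes ran from 3.08 (SE 0.24, limma adjusted p = 0.000686) for Bnip3 to 1.91 (SE 0.22, limma adjusted p = 0.00246) for Pld4. Slc16a3 encodes a lactate exporter, Egln3 an oxygen-sensing prolyl hydroxylase and Aldoc a glycolytic aldolase. Fcer2a and Cd22 encode B cell surface proteins. Ighv14-4 is 1 of a family of similar variable segments and Tpi-rs11 is a copy related to Tpi1, so that reads may be shared and both values are uncertain. The largest falls were those of Chac1, Pck2, Slc7a3, Atf5, Cth, Trib3, Gpt2, Pycr1, Asns, Ddit3, Slc6a9 and Ring1. They ran from -1.71 (SE 0.18, limma adjusted p = 0.00195) for Chac1 to -0.89 (SE 0.12, limma adjusted p = 0.00503) for Ring1. Asns makes asparagine, Pycr1 proline and Cth cysteine, Slc7a3 and Slc6a9 carry amino acids into the cell, and Ddit3, Trib3 and Atf5 are regulators of the stress response. Among these 24 genes, Ighv14-4, Tpi-rs11, Cd22 and Slc6a9 lost their call when single samples were left out, with adjusted p up to 0.0782.

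**Figure D1:**
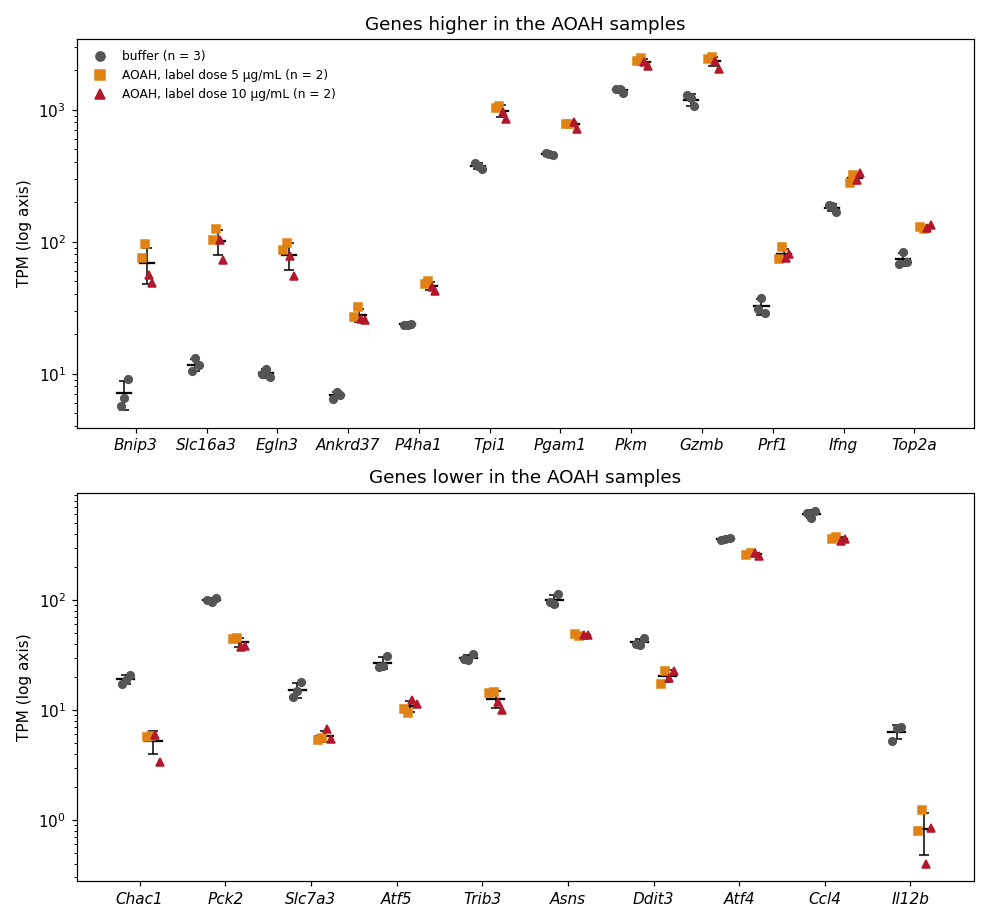
TPM of named genes in each sample on a log axis, with the group mean and SD as a line and bar; points are samples, buffer (n = 3) in grey and AOAH (n = 4) in colour by label dose. In the upper panel every AOAH sample lies above every buffer sample, as with Bnip3 at 48.8 to 96.4 TPM against 5.67 to 9.08 TPM; in the lower panel every AOAH sample lies below, as with Pck2 at 37.7 to 45.4 TPM against 96.5 to 103.8 TPM.

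Glycolysis genes rose almost as a whole. Of 17 measured members 16 were higher and none lower over all genes tested, and 16 were higher when adjusted over the list alone. Tpi1 was at 979.7 ± 99.2 TPM with AOAH (SD, n = 4) and 374.2 ± 19.99 TPM with buffer (SD, n = 3), Pgam1 at 773 ± 38.4 and 461 ± 6.60 TPM, and Pkm at 2310 ± 127 and 1398 ± 63.6 TPM. Slc16a3 was at 101 ± 21.6 and 11.7 ± 1.32 TPM. The median log2 fold change of the list was 0.76 (camera adjusted p = 2.02e-18; adjusted p = 0.232 with an estimated correlation). Of 13 measured hypoxia response genes, 8 were higher and none lower, and 11 were higher when adjusted over the list alone (median 0.73, camera adjusted p = 3.8e-08; adjusted p = 0.276 with an estimated correlation). Besides Bnip3 and Egln3 these included Ankrd37, at 27.7 ± 3.06 against 6.88 ± 0.373 TPM, and P4ha1, a collagen prolyl hydroxylase, at 46.3 ± 3.51 against 23.6 ± 0.322 TPM. None of 21 oxidative phosphorylation genes passed the threshold in limma in either direction, over all genes or over the list alone. The smallest adjusted p among them was that of Sdha, at 412 ± 8.45 and 356 ± 32.7 TPM (adjusted p = 0.0522), and the list did not pass camera (adjusted p = 0.101). With median-ratio scaling it passed as lower (median -0.13, camera adjusted p = 0.00127).

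Cytotoxic effector genes rose in part, while genes induced by the T cell receptor moved both ways. Of 15 measured effector genes 8 were higher and none lower, and 11 were higher when adjusted over the list alone (median log2 fold change 0.54, camera adjusted p = 5.86e-06; adjusted p = 0.365 with an estimated correlation). The median was 0.12 in the fit with the B cell score as a covariate, which was chosen after the data were seen. Gzmb, which encodes the protease granzyme B, was at 2328 ± 198 TPM with AOAH (SD, n = 4) and 1193 ± 121 TPM with buffer (SD, n = 3). Prf1, which encodes the pore protein perforin, was at 80.4 ± 7.57 and 32.4 ± 4.55 TPM, Ifng at 306 ± 22.3 and 181 ± 11.8 TPM, and Tbx21, a transcription factor of effector cells, at 77.9 ± 1.28 and 52.0 ± 4.35 TPM. Granzyme genes are near-identical in part, so that their split of reads is uncertain. Of 29 measured receptor-induced genes 8 were higher and 8 lower, 10 and 10 when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.104). Its median of 0.04 lay above 0 whereas camera placed it lower than other genes. The chemokine genes Ccl3 and Ccl4 fell, from 542 ± 25.1 to 369 ± 14.4 TPM and from 608 ± 47.2 to 361 ± 12.4 TPM, as did Slc3a2, a subunit of amino acid transporters, from 293 ± 11.9 to 205 ± 7.70 TPM. Il2, singled out after its values were seen, was at 20.2 ± 2.51 TPM with AOAH and 27.2 ± 1.84 TPM with buffer (log2 fold change -0.42, SE 0.11, limma adjusted p = 0.0396).

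Of 14 genes of the IL-2 and STAT5 response, 7 were higher and none lower, and 10 were higher when adjusted over the list alone (median 0.32, camera adjusted p = 7.71e-05; adjusted p = 0.276 with an estimated correlation). Besides Gzmb they included Lif, at 46.6 ± 3.58 TPM with AOAH (SD, n = 4) against 27.98 ± 0.919 TPM with buffer (SD, n = 3), Ccnd3 and Il2rb. Among 11 inhibitory receptor genes, Pdcd1 and Lag3 were lower and Ctla4 and Tigit higher, 4 each way when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.383). Median-ratio scaling gave 1 higher and 3 lower. Pdcd1, which encodes PD-1, was at 52.9 ± 4.38 against 65.7 ± 3.27 TPM and Ctla4 at 47.4 ± 4.11 against 31.5 ± 3.32 TPM. Of 14 naive and memory T cell genes, 1 was higher and 1 lower (Id3), likewise when adjusted over the list alone (camera adjusted p = 0.152). The chemokine list passed camera as lower (adjusted p = 0.0195; adjusted p = 0.397 with an estimated correlation), although its median was 0.03, with 2 of 15 members lower, Ccl3 and Ccl4, both over all genes and when adjusted over the list alone. That call was lost with median-ratio scaling (adjusted p = 0.139), quantile normalization (adjusted p = 0.153), no filter (adjusted p = 0.124), TPM rescaled without the 50 most abundant genes (adjusted p = 0.0577) and fry (adjusted p = 0.213). It was also lost without buffer replicate 2 (adjusted p = 0.0528), AOAH replicate 1 (adjusted p = 0.0604) or AOAH replicate 3 (adjusted p = 0.057).

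Cell cycle genes rose in nearly every case. Of 34 members 33 were higher and none lower, all 34 were higher when adjusted over the list alone, and the median was 0.62 (camera adjusted p = 3.44e-21; adjusted p = 0.24 with an estimated correlation). With median-ratio scaling 25 of the 34 were higher. Top2a, a topoisomerase of dividing cells, was at 128 ± 3.72 TPM with AOAH (SD, n = 4) and 73.9 ± 8.60 TPM with buffer (SD, n = 3), and Bub1b, a kinase of the mitotic checkpoint, at 44.5 ± 5.82 and 19.5 ± 1.39 TPM. Ccna2 was at 45.5 ± 3.68 and 25.1 ± 2.61 TPM and Tpx2 at 24.0 ± 1.96 and 13.4 ± 0.838 TPM.

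Genes of lipid synthesis rose in part. Of 15 fatty acid synthesis and activation genes 8 were higher and none lower, and 9 when adjusted over the list alone (median 0.34, camera adjusted p = 0.000272; adjusted p = 0.232 with an estimated correlation). Scd2, a desaturase that makes monounsaturated fatty acids, was at 53.8 ± 9.16 TPM with AOAH (SD, n = 4) and 13.5 ± 2.19 TPM with buffer (SD, n = 3), Fads2 at 2.79 ± 0.469 and 0.660 ± 0.0346 TPM, Acaca at 45.4 ± 2.56 and 33.1 ± 4.59 TPM and Acly at 166 ± 11.7 and 131 ± 11.8 TPM. Of 22 cholesterol synthesis genes 5 were higher and none lower, and 11 when adjusted over the list alone (median 0.25, camera adjusted p = 0.00185; adjusted p = 0.486 with an estimated correlation). These included Stard4, Insig1 and Srebf2, at fold changes of 1.64, 1.34 and 1.14. With median-ratio scaling 2 of the 22 and 4 of the 15 fatty acid genes were higher. Among 7 targets of the sterol-sensing receptor LXR 1 was higher, Pltp, and also over the list alone (camera adjusted p = 0.235). Among 17 genes of phospholipid remodelling and eicosanoids 1 was higher, Lta4h, and 3 over the list alone (camera adjusted p = 0.311). Of these 17 genes, 0 were higher with median-ratio scaling or with the replicate number as a block.

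Stress response genes fell in part. Of 16 members of the unfolded protein and integrated stress response list, 10 were lower and 1 higher, 11 and 1 when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 3.57e-14; adjusted p = 0.232 with an estimated correlation). Asns was at 48.3 ± 0.608 TPM with AOAH (SD, n = 4) and 100.1 ± 11.2 TPM with buffer (SD, n = 3), Atf5 at 10.9 ± 1.23 and 26.9 ± 3.37 TPM, and Atf4, the transcription factor that drives amino acid synthesis genes, at 261 ± 6.48 and 358 ± 7.07 TPM. The member that rose was Atf3, from 18.5 ± 0.839 to 34.2 ± 6.04 TPM, named after its value was seen. The 5 members that did not pass over all genes, also named after their values were seen, were Hspa5, Hsp90b1, Pdia4, Dnajb9 and Sdf2l1, genes of protein folding in the endoplasmic reticulum. Among 12 p53 targets Bbc3 and Gdf15 were lower, 3 when adjusted over the list alone (camera adjusted p = 0.00478; adjusted p = 0.396 with an estimated correlation), a call lost without buffer replicate 2 (adjusted p = 0.0534) or buffer replicate 3 (adjusted p = 0.0688), at a mean TPM of at least 5 (adjusted p = 0.0722) and with fry (adjusted p = 0.209). Of 11 immediate early and heat shock genes Ier3 was higher, and 1 was higher and 1 lower over the list alone (camera adjusted p = 0.78).

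Of 77 ribosomal protein genes 32 were lower and none higher, and 57 were lower when adjusted over the list alone (median -0.14, camera adjusted p = 5.02e-37; adjusted p = 0.232 with an estimated correlation). Rps19 was at 3908 ± 63.3 TPM with AOAH (SD, n = 4) and 4822 ± 276 TPM with buffer (SD, n = 3), and Rpl12 at 2442 ± 74.9 and 3003 ± 41.3 TPM. Rps14, at 5282 ± 114 and 6189 ± 235 TPM, was 0.01 higher on the log2 scale with quantile normalization. Ribosomal protein genes have many processed copies that can share reads. Together they held 21.5% ± 0.548 of TPM with AOAH and 23.9% ± 0.644 with buffer (exact permutation p = 0.0286). Of 15 mitochondrially encoded genes 5 were lower and none higher, likewise over the list alone (median -0.15, camera adjusted p = 3.15e-05; adjusted p = 0.232 with an estimated correlation). With quantile normalization that list did not pass (camera adjusted p = 0.138) and mt-Co1, at 5303 ± 180 and 6190.2 ± 50.9 TPM, was 0.01 higher on the log2 scale.

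**Figure D2:**
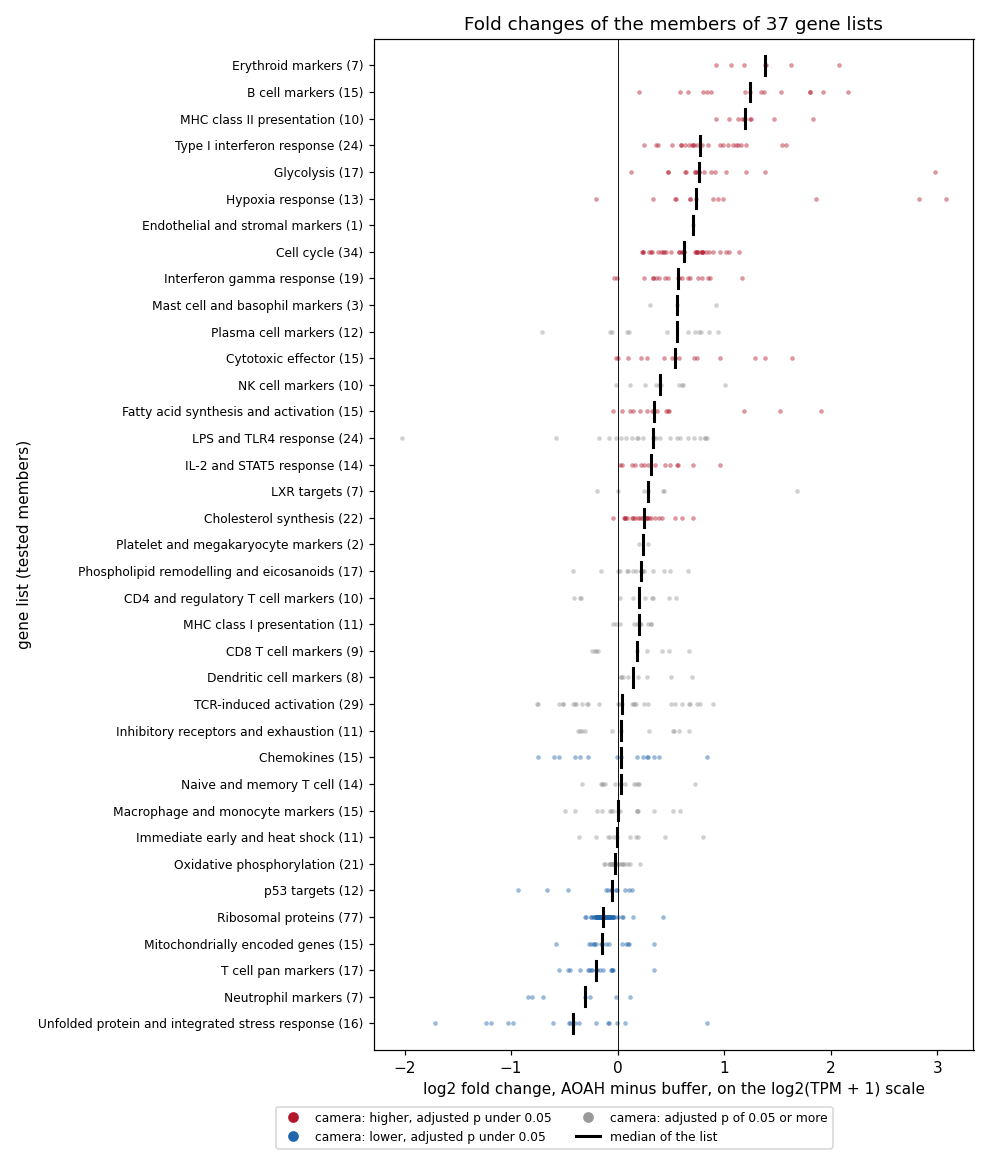
Log2 fold change of each tested member (points) of 37 gene lists, AOAH minus buffer, on the log2(TPM + 1) scale, with the list median as a black line and the number of tested members in brackets; colour gives the camera call at an adjusted p of 0.05. Medians run from 1.38 for the erythroid markers to -0.42 for the unfolded protein and integrated stress response list, and 12 lists are coloured as higher and 7 as lower.

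Markers of cell types differed between the groups as well. Of 15 B cell markers 9 were higher and none lower, and 14 were higher when adjusted over the list alone (median log2 fold change 1.24, camera adjusted p = 8.38e-07; adjusted p = 0.397 with an estimated correlation). Ms4a1, which encodes CD20, was at 49.2 ± 11.8 TPM with AOAH (SD, n = 4) and 13.6 ± 5.08 TPM with buffer (SD, n = 3), Fcer2a at 33.1 ± 5.96 and 7.23 ± 4.49 TPM, Bank1 at 30.5 ± 7.42 and 8.24 ± 3.47 TPM and Spib at 35.7 ± 7.47 and 15.1 ± 4.16 TPM. Of 10 class II presentation genes 9 were higher, and all 10 over the list alone (median 1.19, camera adjusted p = 5.66e-06; adjusted p = 0.396 with an estimated correlation), among them Cd74 at 1417 ± 302 and 528 ± 202 TPM, H2-DMb2, H2-DMa and Ciita. Genes of the H2 families are similar in sequence, and their values are uncertain to that extent. Of 17 T cell markers 8 were lower and 1, Cd2, higher, 10 and 1 when adjusted over the list alone (median -0.20, camera adjusted p = 4.57e-10; adjusted p = 0.253 with an estimated correlation). Cd3g was at 165 ± 7.43 and 225 ± 14.9 TPM, Trbc1 at 260.2 ± 26.7 and 379.8 ± 20.2 TPM and Trbc2 at 5024 ± 423 and 6930.3 ± 577 TPM. Cd2, at 119 ± 2.44 and 93.6 ± 5.55 TPM, did not pass with median-ratio scaling. CD8 T cell markers included 4 higher genes, Eomes, Runx3, Nkg7 and Klrk1, among 9, with 4 higher and 2 lower over the list alone (camera adjusted p = 0.78).

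All 7 measured erythroid markers were higher, also over the list alone (median 1.38, camera adjusted p = 1.98e-05; adjusted p = 0.232 with an estimated correlation), with Hba-a2 at 36.3 ± 8.55 TPM with AOAH (SD, n = 4) and 10.9 ± 1.66 TPM with buffer (SD, n = 3). The paired globin copies share reads. Of 11 erythroid markers with values, these 7 passed the filter. With buffer, Car1 and Hbb-bt were at means of 0.03 and 0.92 TPM, below the filter bound of 1 TPM. They could thus pass the filter through the AOAH samples alone, which favours a rise. Both had no adjusted p in the authors' deposited table. The neutrophil list passed camera as lower (median -0.30, adjusted p = 0.0028; adjusted p = 0.396 with an estimated correlation) with none of 7 members past the threshold over all genes and 1 lower over the list alone. With fry that call was lost (adjusted p = 0.23). S100a9 was at 22.7 ± 7.33 and 40.8 ± 9.15 TPM (limma adjusted p = 0.0505). Of 10 NK cell markers Ncr1 and Klra7 were higher, 3 over the list alone, with a camera adjusted p of 0.05001 that missed the threshold and 0.00775 with median-ratio scaling, where the list passed as higher. Of 15 macrophage and monocyte markers Ly6c2 was higher and Hmox1 lower, also over the list alone (camera adjusted p = 0.386). Single members rose among 10 CD4 and regulatory T cell markers (Tnfrsf18; 1 over the list alone; camera adjusted p = 0.862), 12 plasma cell markers (Sdc1; 7 higher and 1 lower over the list alone; camera adjusted p = 0.311) and 1 endothelial and stromal marker (Pecam1; 1 over the list alone; camera adjusted p = 0.166). No member of the 8 dendritic cell, 3 mast cell and basophil or 2 platelet and megakaryocyte markers passed over all genes in limma, and 2 mast cell and basophil markers rose over the list alone, with camera adjusted p of 0.78, 0.216 and 0.848.

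**Figure D3:**
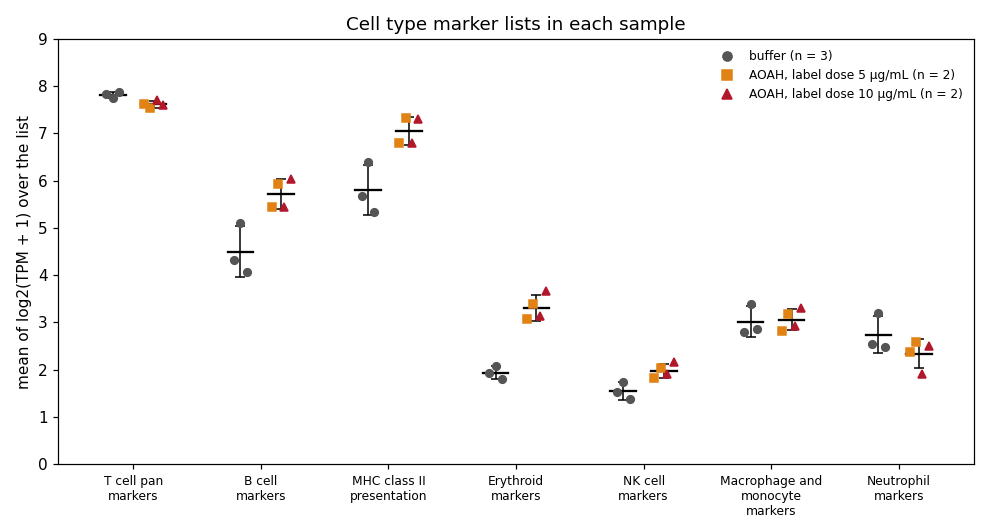
Mean log2(TPM + 1) over the tested members of 7 lists in each sample, with group mean and SD as a line and bar; grey points are buffer (n = 3) and coloured points AOAH (n = 4) by label dose. The B cell score lies between 5.45 and 6.03 with AOAH and between 4.06 and 5.10 with buffer, whereas macrophage and monocyte scores overlap.

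Interferon response genes rose in part. Of 24 type I interferon response genes 11 were higher and none lower, and 22 when adjusted over the list alone (median 0.77, camera adjusted p = 3.8e-08; adjusted p = 0.396 with an estimated correlation). Isg15 was at 33.6 ± 6.11 TPM with AOAH (SD, n = 4) and 15.3 ± 3.12 TPM with buffer (SD, n = 3), Usp18 at 11.4 ± 1.66 and 4.75 ± 1.04 TPM, and Ifi27l2a at 179 ± 43.0 and 60.9 ± 24.6 TPM. Of 19 interferon gamma response genes 13 were higher and none lower, and 16 over the list alone (median 0.57, camera adjusted p = 7.25e-08; adjusted p = 0.396 with an estimated correlation). Gbp2 was at 291 ± 22.0 and 183 ± 9.11 TPM and Tgtp1, which has a near-identical copy and is uncertain, at 163 ± 15.95 and 88.8 ± 9.47 TPM. Of 11 class I presentation genes Tap1 and Psmb8 were higher, likewise over the list alone (camera adjusted p = 0.111), but 0 of the 11 were higher with median-ratio scaling. Of 24 measured genes of the response to lipopolysaccharide, Icam1 was higher and Il12b lower, 5 higher and 2 lower over the list alone (median 0.33, camera adjusted p = 0.537). Il12b was at 0.820 ± 0.343 and 6.36 ± 0.940 TPM.

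In an added fit, chosen after the data were seen, the B cell score of each sample was a covariate, and no gene passed the threshold in limma. The median standard error of the raised glycolysis and hypoxia genes was 0.17 in that fit and 0.08 without the covariate, and 53 of the 1416 genes turned direction. Glycolysis passed camera at a median log2 fold change of 0.79 (adjusted p = 2.31e-23), against 0.76 without the covariate, hypoxia at 0.94 (adjusted p = 1.18e-10), against 0.73, and cell cycle at 0.45 (adjusted p = 1.26e-16), against 0.62. The stress response list was at -0.30 (camera adjusted p = 2.24e-06), against -0.42 without the covariate. Cytotoxic effector genes passed at a median of 0.12 (camera adjusted p = 0.00683), against 0.54 without the covariate, and interferon gamma response genes at 0.14 (adjusted p = 0.0111), against 0.57. The B cell list, whose own mean was the covariate, was at 0.07 by construction (camera adjusted p = 0.936). Calls were lost with medians near 0 for class II (0.01, camera adjusted p = 0.666), type I interferon (0.08, adjusted p = 0.697) and T cell (-0.06, adjusted p = 0.246) genes. The call of the mitochondrially encoded list was lost at a median of -0.12 (camera adjusted p = 0.0794), against -0.15. With the covariate 6 lists newly passed camera as lower: macrophage and monocyte (-0.75, adjusted p = 3.37e-08), dendritic cell (-0.38, adjusted p = 0.00154), plasma cell (-0.42, adjusted p = 0.0111), naive and memory T cell (-0.19, adjusted p = 0.00723), lipopolysaccharide response (-0.29, adjusted p = 5.86e-05) and class I presentation (-0.22, adjusted p = 0.000108). In total 19 of 37 lists passed camera with its preset correlation of 0.01, and none passed with an estimated correlation. At least 19 lists also passed in 8 of the 35 ways to split the samples into 4 and 3, the real split included, so the count of lists alone does not set these groups apart.

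The second comparison set the 2 AOAH samples with a label dose of 10 µg/mL against the 2 with 5 µg/mL. The glycolysis and hypoxia genes that were raised over buffer were, if anything, higher at 5 µg/mL, as with Bnip3 at a mean of 85.5 TPM against 52.3 TPM. No single gene differed at an adjusted p of 0.05 in limma, with or without the robust setting. At an unadjusted p under 0.05 there were 429 genes, where chance gives 625.5, and the smallest adjusted p was 0.126. The named genes with the smallest p were Msantd2, Ovca2, Trbv29, Ccl1 and Bcat1 on the higher side at 10 µg/mL and Klhdc1, Fmc1, Dhodh, Ciart and Cacna1a on the lower side. Klhdc1 was at a mean of 11.3 TPM at 5 µg/mL and 3.19 TPM at 10 µg/mL (log2 difference -1.55, SE 0.16, limma adjusted p = 0.126). By camera, the hypoxia (median log2 difference -0.25, adjusted p = 6.6e-10), glycolysis (-0.14, adjusted p = 2.05e-10) and ribosomal (-0.05, adjusted p = 1.15e-14) lists were lower at 10 µg/mL. The cholesterol synthesis (0.15, adjusted p = 7.18e-05), cell cycle (0.12, adjusted p = 1.62e-07) and T cell (0.07, adjusted p = 0.0121) lists were higher. None of these list calls held with an estimated correlation (adjusted p = 0.971 for each). Both samples at 10 µg/mL also listed more genes above 0, 21345 and 21728, than the other 5 samples, at 18679 to 19405, and the labels name no run, so that dose and library differences cannot be told apart.

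The third comparison used the receptor repertoire table, which lists clonotypes, clones and diversity measures for each sample. T cell receptor beta clonotypes were fewer with AOAH, 300.5 ± 22.8 (SD, n = 4) against 467 ± 52.4 (SD, n = 3), as were alpha clonotypes, 365 ± 27.1 against 472 ± 38.4. All clones of a sample numbered 27243 to 32482 with AOAH and 31822 to 46642 with buffer. Per 100 of them the alpha clonotype difference turned to 0.00555 (adjusted exact permutation p = 0.914) and that of beta clonotypes was -0.189 (adjusted exact permutation p = 0.176). Beta clones per clonotype were 79.8 ± 13.03 with AOAH and 74.7 ± 9.42 with buffer (exact permutation p = 0.571). Immunoglobulin heavy chain clonotypes were more numerous, 1351 ± 247 against 739 ± 262, as were clonotypes of the chain that the table names IGL, 840.3 ± 71.2 against 569 ± 127. Heavy chain clones made up 5.39% ± 1.40 of all clones with AOAH and 2.34% ± 1.17 with buffer (exact permutation p = 0.0571). Their exact binomial 95% intervals, which cover counting error only, ran from 3.73% to 4.16% in the lowest AOAH sample and from 3.46% to 3.88% in the highest buffer sample. IgM took 80.7% ± 0.771 of heavy chain clones with AOAH and 75.2% ± 2.99 with buffer. Of 20 measures, 11 reached p = 0.0286 in the two-sided exact permutation test, the smallest p that 35 splits allow, and none passed after adjustment (adjusted p = 0.0519). Whether a clone is a read or a molecule is not given in the sources used here.

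Beta chain clonality, which is 1 for a single clone, was 0.973 ± 0.00387 with AOAH (SD, n = 4) and 0.973 ± 0.00343 with buffer (SD, n = 3), with an exact permutation p of 0.743. In the expression table the beta segment Trbv14, named outside the naming rule because it encodes the pmel receptor's beta chain, held at least 99.2% of all Trbv transcripts in each sample. It was at 19501.5 ± 1685 TPM with AOAH and 28215 ± 3371 TPM with buffer (exact permutation p = 0.0286). Beta clones made up between 76.4% and 91.7% of all clones in a sample, 89.4% ± 3.44 with buffer and less in each of the 4 AOAH samples (exact permutation p = 0.0571).

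**Figure D4:**
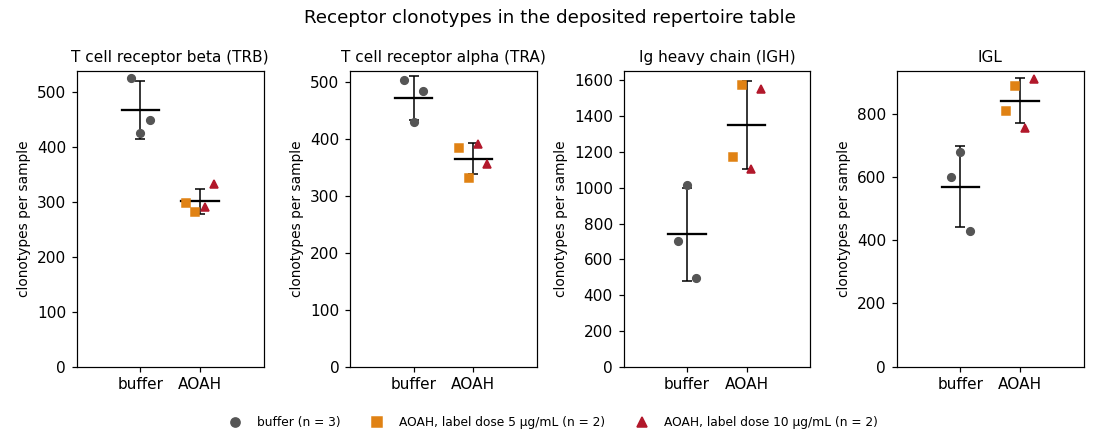
Clonotypes per sample in the deposited repertoire table for 4 receptor chains, with group mean and SD as a line and bar; grey points are buffer (n = 3) and coloured points AOAH (n = 4) by label dose. Beta clonotypes lie between 281 and 333 with AOAH and between 426 and 526 with buffer, and heavy chain clonotypes between 1107 and 1574 against 495 to 1016.

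The authors' deposited table of a single comparison lists 26637 genes, of which 1098 had an adjusted p under 0.05, 737 with a positive and 361 with a negative fold change. Its header names no direction. Of 10837 genes that could be matched by symbol and were tested in both, 1066 passed in the authors' deposited table, 1321 in the limma fit and 762 in both, these all with the sign of AOAH minus buffer. In the authors' deposited table Slc16a3 had a log2 fold change of 3.13 (SE 0.12), Gzmb 0.93 (SE 0.07), Chac1 -1.81 (SE 0.23) and Pck2 -1.34 (SE 0.10). Other genes that passed in the limma fit and are named above did not pass there. Among them were Nkg7 (DESeq2 adjusted p = 0.511), Klrk1 (adjusted p = 0.161), Tap1 (adjusted p = 0.105), Psmb8 (adjusted p = 0.12), Klra7 (adjusted p = 0.63), Lta4h (adjusted p = 0.524) and Cd2 (adjusted p = 0.169). Ighv14-4 and Tpi-rs11, among the 12 largest rises in limma, and Gdf15 had no adjusted p there. Positive calls made up 67.1% in the authors' deposited table. In limma 82.3% were higher with TPM as deposited and 59.0% with median-ratio scaling. The sets of genes also differed, with 11616 adjusted p-values in the authors' deposited table and 12510 genes in the limma fit.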

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

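Of the tests in this part, those with the B cell score as a covariate, with odd against even replicate numbers as a block, on dose growth, on the difference between B cell and other scores, on lipopolysaccharide and without the 50 most abundant genes were chosen after the result was seen.

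AOAH replicate 4 lay far from the other 3 AOAH samples in 3 of 81 values tested, where chance gives 4.05: Chac1, with a gap of 0.904 of the group's range, the unfolded protein and integrated stress response score (0.840) and the IgM share of heavy chain clones (0.910). By camera at its preset correlation, 6 lists differed between the label doses, although none did with an estimated correlation (adjusted p = 0.971). The log2 differences of 10 minus 5 µg/mL were 0.0695 for T cell markers, 0.1205 for cell cycle, -0.139 for glycolysis, -0.255 for hypoxia response, 0.148 for cholesterol synthesis and -0.0509 for ribosomal proteins.

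The 24 raised glycolysis and hypoxia genes had a median log2 fold change of 0.84, and with median-ratio scaling it was 0.74 and all 24 stayed past the threshold, which speaks against scaling as the source. With the B cell score as a covariate 0 of the 24 stayed past the threshold, as their median standard error grew from 0.0804 to 0.166 while the median fold change was 0.85. The first criterion needed the calls and the median to point the same way, which they did not, so it gave no decision. A criterion added afterwards used the mean of the set. It was 1.12 higher with AOAH, and 1.14 higher (95% interval 0.605 to 1.68, 4 residual degrees of freedom) with the covariate. That interval lies just above the bound of 0.561 (0.5 of the first value). However, the 24 genes were picked as higher in these same data, and this criterion followed the first result. It therefore does not by itself decide whether the share of B cells is the source. The glycolysis list was fixed beforehand. Its score was 7.60, 7.67 and 7.64 in buffer replicates 1 to 3, with B cell scores of 4.32, 5.10 and 4.06. It was 8.58, 8.64, 8.53 and 8.38 in AOAH replicates 1 to 4, with B cell scores of 5.45, 5.94, 5.45 and 6.03. These values argue against the share of B cells as the whole source for that list, though B cell scores of the groups do not overlap. The same covariate took the median of the class II list from 1.19 to 0.01, a list whose scores ran with the B cell scores across samples. An effect that grows with the label dose was not seen: the median of 10 minus 5 µg/mL was -0.18, with limma camera p = 1.53e-16, and p = 0.0531 with an estimated correlation, and dose cannot be told apart from the library set. A response of the cells to AOAH could account for the rise, and the groups of the design do not separate it from a response to another part of the protein preparation.

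B cell and class II genes were higher and T cell genes lower with AOAH. The B cell score minus the T cell score was 1.42 higher with AOAH (exact permutation p = 0.0286). AOAH minus buffer, the B cell score was at 1.22 and the T cell score at -0.201. Scaling of a whole sample moves both scores nearly alike and so cannot make this difference. The value of 1.43 with median-ratio scaling (exact permutation p = 0.0286) was thus fixed in advance and adds no support. The difference restates the pattern that prompted it and does not show whether the T cell fall alone depends on scaling. Taken alone, the T cell list was also lower with median-ratio scaling. There 9 of 17 members were lower (median -0.31, camera adjusted p = 3.17e-08 at the preset correlation). The B cell score also rose by 1.18 more than the macrophage and monocyte score (exact permutation p = 0.0286, the smallest that 35 splits allow). Both changes had been seen before, so this test restates that those 2 lists were not raised alike and adds no support. Many macrophage and monocyte markers were low, as with Csf1r at a mean of 3.64 TPM, where the log2(TPM + 1) scale damps a rise. Other cell types were not compared in this test. Lipopolysaccharide in the protein preparation could not be judged: the response list did not pass camera (limma, adjusted p = 0.537), with 1 member higher and 1 lower of 24, and 6 higher and 2 lower with odd against even replicate numbers as a block (adjusted p = 0.415), while with the B cell score as a covariate the list passed as lower (median -0.29, adjusted p = 5.86e-05). Whether cells were present in other numbers or transcribed more per cell was not tested.

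Of the calls, 82.3% were higher with AOAH. With median-ratio scaling 59.0% were, but that scaling centres the median by construction and so does not test why. With TPM rescaled without the 50 most abundant genes 70.7% were (791 higher, 328 lower), and without mitochondrial and receptor genes 77.9%, so that abundant transcripts could account for a part of the imbalance. The 50 most abundant genes held 26.7% of TPM with buffer and 23.8% with AOAH (exact permutation p = 0.0286).

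The count of genes was not matched by regrouping: 1 of 35 splits gave 1416 or more, the real split, and the highest of the others gave 4. The count of 19 lists was matched or passed in 8 of 35 splits, with up to 22, so chance cannot be excluded for it.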

How the results depend on the processing

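The fits with a B cell score, with odd against even replicate numbers and without the 50 most abundant genes were chosen after the result was seen; all others were planned. The count of 1416 genes (1166 higher, 250 lower) fell to 557 (449 and 108) without a filter, to 890 (757 and 133) without a trend, to 168 (123 and 45) with 5 µg/mL only and to 296 (214 and 82) with 10 µg/mL only; the dose fits hold fewer samples, and for the others the cause was not tested. Quantile normalization gave 658 higher and 607 lower, and median-ratio scaling 660 and 458; both take out the shift of the median by construction. With the B cell score there were 0 genes (0 higher, 0 lower), Tap1 was at -0.0331 and the B cell list, whose mean is that score, had a median of 0.0733 and was lower in camera. With quantile normalization Rps14 was at 0.0137 and mt-Co1 at 0.0141. Leaving out single samples gave 628 to 1354 genes (495 to 1176 higher, 133 to 194 lower) and 18 to 21 lists. Of 109 named genes 81 stayed past the threshold in all of these fits, 28 did not in at least 1 and 0 changed sign. All other settings gave counts within 1.5 times.

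The 19 lists became 0 with an estimated correlation and 18 to 21 in all other settings; 11 kept their call throughout and 8 lost it at least once. The mitochondrially encoded list has no value where its genes were left out, and lists were not tested with robust eBayes, which camera does not take. The dose comparison gave 0 genes, 59 without a filter, 50 of these with a mean TPM under 1, and 1 with a pseudocount of 0.1 (Gm13166, named outside the naming rule); leaving out single samples gave 0 to 1, the 1 being Trav7n-5, also named outside that rule, without AOAH replicate 1, where the lone sample at 5 µg/mL was at 0 and is assumed to vary like the other groups. On the log2 scale heavy chain clonality differed by 0.0265, against -0.000172 on the linear scale, and alpha clonotypes per 100 clones by 0.00555, against -107 clonotypes; the cause was not tested. No repertoire measure passed in any setting, and with a sample left out too few splits remain for the exact permutation test to reach p = 0.05.

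With the replicate number as a replicate block 1060 genes passed (860 higher, 200 lower) and 19 lists. Deviations of same-numbered samples correlated at 0.132, 0.174 and 0.0683, each the highest value of that buffer replicate. Pairs with different numbers ran from -0.162 to 0.0821. AOAH replicate 3 correlated slightly better with buffer replicate 1 (0.0708) than with its own number. The labels do not say what a number marks, so whether the numbers pair the samples is left open, and the main fit did not use them. The depth of each sample is unknown; in the authors' deposited table the mean signal of Aoah over samples was 23.7 scaled counts, which limits the precision of genes at that level.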

Other observations

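The tests on aminoacyl-tRNA synthetases, the serine pathway and the receptor alpha chain were chosen after the result was seen.

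Genes that charge transfer RNA and genes that make serine were lower with AOAH in part. Of 19 cytosolic aminoacyl-tRNA synthetase genes 7 were lower and none higher in limma, among them Sars at 314 ± 7.57 TPM with AOAH (SD, n = 4) and 469 ± 24.4 TPM with buffer (SD, n = 3), and Cars at 77.3 ± 1.48 and 111 ± 6.72 TPM. Of 11 serine and one-carbon genes 8 were lower, among them Psph at 62.7 ± 6.40 and 92.8 ± 4.27 TPM and Shmt2 at 402 ± 12.7 and 519.6 ± 22.8 TPM. These genes, and the next 3, were named outside the naming rule after their values were seen. Hars, at 143 ± 4.64 and 143 ± 5.10 TPM, Kars and Vars did not pass. The hypothesis was that amino acid response genes outside the fixed stress list fell as a group. A first test on all 30 genes found 15 lower (limma camera p = 0.0288 with an estimated correlation), exactly the 50% its prediction asked for; the prediction was then narrowed, after that result was seen, to the 26 genes that were neither in the stress list nor seen before. Of these 11 were lower (limma camera p = 4.87e-10, and p = 0.0506 with an estimated correlation), which does not decide the hypothesis. With an estimated correlation the 11 serine and one-carbon genes had limma camera p = 0.00754 and the 19 synthetase genes p = 0.0861.

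Alpha chain clones were far fewer than beta clones in every sample, 3.70 to 4.88 per 100 beta clones. The hypothesis was that the transgenic chains are transcribed at different levels. The Trav7 family reached at most 0.832% of the TPM of Trbv14 in a sample, but segments and clones come from the same libraries, so this does not test the hypothesis apart from what prompted it.

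B cell scores were 5.45, 5.94, 5.45 and 6.03 in AOAH replicates 1 to 4 and 4.32, 5.10 and 4.06 in buffer replicates 1 to 3, so the even-numbered samples had the higher scores in both groups. Sample weights ran from 0.513 for buffer replicate 1 to 1.41 for buffer replicate 2.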
